A study of Drosophila melanogaster with 2 samples.

How the data were processed

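Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to whole Drosophila melanogaster embryos of both sexes aged 6 to 22 hours, from a transgenic line that makes the homeodomain protein B-H2 with green fluorescent protein at its C terminus. The group held 2 biological replicates, numbered 1 and 3 in the labels. Chromatin had been sheared by sonication to a size range of 200 to 800 bp, per the labels. The labels name B-H2 as the antibody target and the assay as transcription factor ChIP-seq, but the free-text description of both samples calls them an input control. A separate experiment is also listed as a possible control. Nothing in the peak lists settles that conflict, and the values are reported under the assay and antibody labels. One age entry in the labels is unreadable as a time, so the hours were taken from the source label.

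The authors deposited 4 peak lists in coordinates of genome build dm6, per the labels. The peak caller, its version and the threshold of the irreproducible discovery rate (IDR, a measure of how well peak ranks repeat between replicates) are not given in the sources used here. Each replicate had a list of 30000 peaks called permissively as IDR input, and another list of 30000 peaks came from the pooled alignments of both replicates. The same control alignment served both replicates and the pool, per the deposited file descriptions. The fourth list, the authors' optimal IDR-thresholded set, held 4277 peaks. Each peak carries a signal value from the authors' peak caller, which is used here only to rank and describe peaks within a list. Each peak also carries a deposited −log10 q-value, which saturates: all 4277 IDR peaks hold the highest value of the pooled list, 4.09, so it ranks nothing among them. The deposited score and p-value columns hold a constant placeholder. All 4277 IDR peaks are rows of the pooled list, and they are exactly its 4277 peaks of highest signal, from 112 to 3978. Read depth is unknown, since the peak lists give no read counts. Exact intervals given here cover the counting of peaks or genes only.

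Reference sequence came from the dm6 assembly, and gene models from Ensembl release 115 (BDGP6.54). All peaks of the 4 lists ended within the arms of that assembly. There were 13968 protein-coding genes with 19630 distinct transcription start sites (TSSs). Promoter means a summit within 1 kb of such a TSS, and the remaining summits were assigned in the order 5' UTR, CDS, 3' UTR, intron and intergenic, from protein-coding genes only, so an intergenic summit can lie in a non-coding gene. Distal means outside promoters. IDR peaks were compared with low-ranked peaks, the 24843 pooled peaks that overlap no IDR peak. These are weaker peaks of the same immunoprecipitation, not a separate control. Another 880 pooled peaks overlapped an IDR peak without being one and entered neither set. Of the IDR peaks, 22 shared their interval with another summit, and 1 had its summit outside its interval.

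Shares were compared with Fisher's exact test, two-sided, with the conditional odds ratio and its 95% interval. Intervals of shares are exact (Clopper-Pearson). P-values were adjusted by the Benjamini-Hochberg method within each family (6 annotation classes, 7 arms, 10 sites, 2080 6-base sites, 17 gene lists), at a threshold of 0.05. Replicate overlap required 1 bp, between the 4277 peaks of highest signal in each list, and chance came from 1000 circular shifts along each arm (one-sided permutation test). Correlations of signal across peaks used 100000 random pairings. Sites were searched on both strands within 50 bp of the summit. A second comparison drew up to 2 low-ranked windows per IDR peak from the same 5% bin of GC content, which gave 8552 windows. Another used flanks 200 to 300 bp from the same summits. Neighbouring genes can share a peak and peaks cluster along the genome, so p-values across genes or peaks treat as independent items that are not, and they do not measure spread between embryos. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.

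The gene lists, the sites and the rule for named genes were fixed before the data were examined. The rule names B-H1 and B-H2, the 20 IDR peaks of highest signal by their nearest TSS, and up to 4 members per list with the strongest IDR summit within 1 kb. It also names the 5 windows of 50 kb with the most IDR summits, and the 5 strongest peaks of each replicate that overlap none in the other. Of the symbols in the lists, 8 matched no current gene symbol and were not used. Lists of sensory organ, neuronal, glial, muscle, epidermal, gut and germline genes stand for the tissues of a whole embryo. Alternatives covered the overlap rule, the number of peaks, each replicate alone, merging of overlapping peaks, TSS and site windows, comparison sets and the gene background.

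The calculations were tested on simulated data. With 70.2% of 4277 peaks kept in place, 71.9% were found shared. A simulated TAATTG share of 12.5% was recovered as 12.5%, which checks only that the search finds sites written into windows. A simulated list of 20 genes among 13968 with a true share of 50% passed an unadjusted p of 0.05 in 64% of 200 simulations, and a list of 90 genes in 99%. At the base rate of 26.9%, lists of either size passed in 3.5%.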

Results

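B-H2 and its neighbour B-H1 are the Bar homeodomain proteins of Drosophila, known for roles in eye, external sense organ and neuron development. The data map where GFP-tagged B-H2 was recovered on chromatin in whole embryos of 6 to 22 hours. The single group, B-H2-GFP embryo, had 2 biological replicates and no second condition. The comparisons are therefore between the replicates, and between IDR peaks and weaker peaks. The labels conflict on whether these libraries are the immunoprecipitation or its input control, and a separate experiment is listed as a possible control. Each replicate list and the pooled list held 30000 peaks. The authors' IDR set held the 4277 pooled peaks of highest signal, 14.3% of the pooled list. Its median signal was 168, against 44.6 for the whole pooled list. The pooled and IDR lists had a median peak width of 384 bp. Read depth is unknown for all lists.

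The strongest peaks recurred in both replicates and lay mostly at promoters. The first was 96 bp from the TSS of CG14100 (3L, 19590413 to 19590833, signal 3978), ranked 2 in replicate 1 and 1 in replicate 3. The next lay 135 bp from the TSS of mRpL41 (2R, 15217565 to 15217996, signal 3802), a protein of the mitochondrial ribosome. Rank 3 was an intronic peak in CG11050, and rank 4 lay 147 bp from the TSS of Gapdh2 (X, 15867775 to 15868213, signal 2451). A peak 199 bp from the TSS of Eno, which encodes enolase, ranked 14 (2L, 1727701 to 1728135, signal 1424). Among the 20 IDR peaks of highest signal, 15 were promoter peaks, 4 were intronic and 1 was intergenic. All 20 ranked within the top 59 of replicate 1 and the top 25 of replicate 3. Their choice by pooled signal draws on both replicates, so some of this recurrence follows from the choice.

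Other promoter peaks in this set had their nearest TSS at CG9663, Pdrg1, the arginine methyltransferase gene Art3, the kinase gene Lk6, CG11309, the translation factor gene eIF6, CG1888, CG1635, CG5611, the tRNA modification gene Tcs5 and the glycosylation gene Alg3. The intronic peaks lay in CG11050 (2L, 6612348 to 6612955, signal 3097), in the kinase gene Tlk (X, 3742029 to 3742436, signal 1907), in Trl (3L, 14759311 to 14759750, signal 1465) and in the forkhead gene CHES-1-like (X, 7706794 to 7707156, signal 1367). Trl encodes GAGA factor, and the TSS nearest to its intronic peak was that of CG42507, 1541 bp away. The peak classed as intergenic lay in the non-coding gene lncRNA:Vinr, and its nearest protein-coding TSS, of CG4004, was 5087 bp away.

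The replicates shared most of their strong peaks. Of the 4277 peaks of highest signal in replicate 1, 3117 (72.9%, 95% interval 71.5 to 74.2) overlapped one of the 4277 strongest in replicate 3. Shifted lists overlapped in 2.08% on average and at most 2.83% (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). Shifting also moves peaks off promoters, where the strong peaks of either replicate were concentrated. The shifts therefore test overlap against random positions along each arm. They cannot tell whether the replicates agree on which promoters are strong, since 2 lists concentrated at promoters would overlap more than shifted ones. Of the 4277 IDR peaks, 4227 (98.8%) had a peak in both replicate lists. The IDR peaks are the strongest of the pool, which holds both replicates, so that match was largely fixed in advance. Summits of the 4227 lay a median of 27 bp apart. Across these peaks, signal in the 2 replicates correlated with Spearman's rho = 0.62 and Pearson's r = 0.74 on the log10 scale (permutation p = 1e-05 for each, the smallest that 100000 pairings can give). Some IDR peaks were matched to the same replicate peaks and so entered with the same values. Peaks are not independent replicates, and the IDR set was chosen on pooled signal, which narrows the range over which it can correlate. Both replicate lists also used the same control alignment, whose part in their agreement was not tested.

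**Figure D1:**
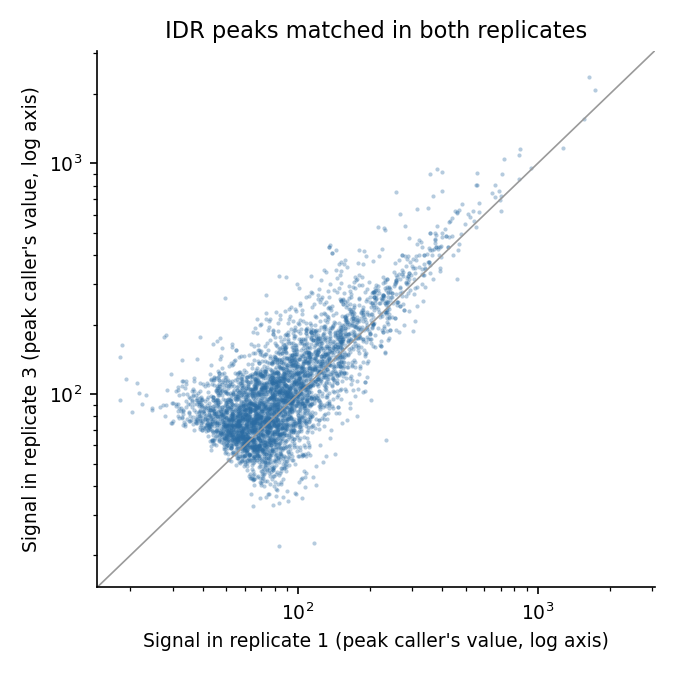
Signal of the 4227 IDR peaks matched in both replicates, replicate 1 on the horizontal and replicate 3 on the vertical axis, both logarithmic and in the peak caller's own units; the line marks equal values. Signal in replicate 3 rises with that in replicate 1, with wide scatter (Spearman's rho = 0.62).

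Peaks strong in 1 replicate and without any overlapping peak in the other were few. They made up 73 of the 4277 strongest peaks of replicate 1 (1.71%) and 140 of those of replicate 3 (3.27%). In replicate 3 the strongest were near the TSS of RpL34a (3R, 26059225 to 26059496, rank 260), trc (3L, 19834246 to 19834430, rank 346), Su(H) (2L, 15039387 to 15039533, rank 612), Sfmbt (2L, 13176716 to 13177079, rank 706) and Tbcd (2L, 2147403 to 2147531, rank 727). In replicate 1 they were near Msp300 (2L, 5107941 to 5108058, rank 583), mgr (3R, 11409737 to 11410126, rank 584), Coq7 (X, 6770946 to 6771335, rank 740), PheRS-m (2R, 13968000 to 13968389, rank 932) and CG17075 (2L, 267584 to 267722, rank 952). All 10 summits lay within 1 kb of a TSS.

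IDR peaks were concentrated at promoters. Of 4277 summits, 3098 (72.4%, 95% interval 71.1 to 73.8) lay within 1 kb of a protein-coding TSS, against 34.9% of low-ranked peaks and 19.7% of genomic bases. The odds ratio was 4.90 (95% interval 4.56 to 5.27, Fisher's exact test, p below the smallest number the software holds). Introns held 18.4% of IDR summits against 42.5% of low-ranked ones (odds ratio 0.304, interval 0.280 to 0.330), and intergenic sequence 7.72% against 16.9% (0.411, interval 0.364 to 0.462). Coding sequence (0.304% against 1.53%) and 3' UTRs (0.842% against 3.59%) were also lower, with adjusted p = 1.54e-13 and 1.90e-27 by Fisher's exact test. 5' UTRs did not pass (0.351% against 0.527%, adjusted p = 0.158, Fisher's exact test). The promoter share rose with signal, from 64.4% in the 855 IDR peaks of lowest signal to 82.5% in the 856 of highest signal (odds ratio 2.60, interval 2.06 to 3.28, Fisher's exact test, p = 2.08e-17). Of the 3098 promoter summits, 2361 (76.2%, interval 74.7 to 77.7) were upstream of the nearest TSS. Part of that share follows from gene layout: 1033 of the 3098 (33.3%) lay between divergent TSSs, upstream of the genes on both sides. Over all 3098 the median distance to the TSS was 94 bp.

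**Figure D2:**
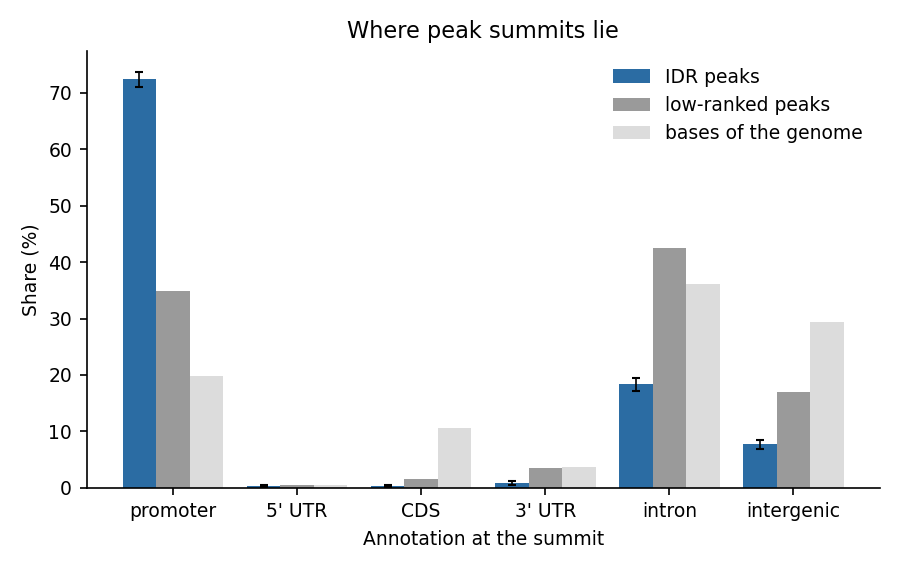
Share of summits (%) in each annotation class for 4277 IDR peaks (with exact 95% intervals), 24843 low-ranked peaks and all bases of the genome. Promoters hold 72.4% of IDR summits against 34.9% of low-ranked summits, and introns 18.4% against 42.5%.

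Over the arms, the X chromosome was under-represented among IDR peaks against low-ranked peaks and arm length, but near its share of genes. It held 663 of the 4238 IDR peaks on X, 2L, 2R, 3L and 3R (15.6%, interval 14.6 to 16.8) against 18.2% of low-ranked peaks (odds ratio 0.835, interval 0.763 to 0.913, Fisher's exact test, p = 6.24e-05). The X makes up 17.8% of the length of these arms and holds 15.8% of their protein-coding genes. The embryos were of both sexes, and the part of X copy number in these shares was not tested. Among promoter peaks alone the shares were 15.1% and 18.8% (odds ratio 0.769, interval 0.685 to 0.861). Chromosome 2R was over-represented against low-ranked peaks (19.9% against 17.6%, adjusted p = 0.00151, Fisher's exact test), with 18.4% of the assembled length. Chromosome 4 was under-represented against low-ranked peaks (0.912%, interval 0.649 to 1.24, against 1.46%, adjusted p = 0.00828, Fisher's exact test). It was near its share of the assembled length, 0.980%. No IDR peak lay on Y.

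No enrichment of the Bar-type site TAATTG was detected at IDR summits. It lay within 50 bp of 370 IDR summits (8.65%, interval 7.83 to 9.53) and of 8.73% of low-ranked summits (odds ratio 0.990, interval 0.880 to 1.11, adjusted p = 0.907, Fisher's exact test). None of the 20 strongest peaks held it. TAAACG, the other Bar-type site, was at 5.49% against 4.61% (odds ratio 1.20, adjusted p = 0.0281, Fisher's exact test), and TAATTT at 19.0% against 14.9% (odds ratio 1.33, adjusted p = 2.98e-10, Fisher's exact test). IDR windows had less GC, 39.6% against 42.0%. Against GC-matched windows neither passed (TAAACG odds ratio 1.18, adjusted p = 0.117, TAATTT odds ratio 1.05, adjusted p = 0.374, Fisher's exact tests). TAATTA (6.94%) and CAATAA (10.6%) passed neither against low-ranked peaks nor against GC-matched windows. Against flanks of the same summits TAATTA passed (5.79% in flanks, odds ratio 1.21, interval 1.04 to 1.41, adjusted p = 0.0190, Fisher's exact test), and the other 4 of these sites did not. In the stronger part of the IDR peaks (the 2138 of highest signal) TAATTA also passed against low-ranked peaks, without GC matching (8.37% against 6.09%, odds ratio 1.41, adjusted p = 0.000155, Fisher's exact test).

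Sites of promoter factors were enriched instead. TATCGA, part of the site bound by the promoter and insulator factors DREF and BEAF-32, lay at 12.3% of IDR summits (interval 11.3 to 13.3) against 5.18% of low-ranked ones (odds ratio 2.57, interval 2.30 to 2.86, adjusted p = 3.67e-58, Fisher's exact test). GGTCAC, part of the site of the core promoter factor M1BP, was at 4.63% against 2.75% (odds ratio 1.72, adjusted p = 1.16e-09, Fisher's exact test). Both held against GC-matched windows, with odds ratios of 2.53 and 2.03. These ratios include the different promoter shares of the peak sets. Among promoter peaks alone the odds ratio was 2.03 for TATCGA (interval 1.79 to 2.29) and 1.33 for GGTCAC (5.75% against 4.37%, interval 1.10 to 1.61). At distal peaks it was 1.01 for TATCGA (interval 0.711 to 1.39) and 0.904 for GGTCAC (interval 0.542 to 1.43). CACACA repeats were less frequent at IDR summits (9.49% against 12.2%, odds ratio 0.753, adjusted p = 4.72e-07, Fisher's exact test), and GAGAGA (4.28% against 5.05%) and the Zelda site CAGGTA (1.71% against 1.87%) did not pass against low-ranked peaks. Against flanks both were lower (5.32% and 2.42% in flanks, adjusted p = 0.0190 for each, Fisher's exact tests), and TATCGA and GGTCAC were higher (odds ratios 2.81 and 1.88). GAGAGA was also lower in the stronger part of the IDR peaks (3.70% against 5.05%, adjusted p = 0.00986, Fisher's exact test). In the screen of 2080 sites against GC-matched windows, 223 were more and 183 less frequent. CGATAG led (9.73% against 3.04%, odds ratio 3.44, interval 2.92 to 4.05), followed by TATCGA, ATCGAT and ACACTG.

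**Figure D3:**
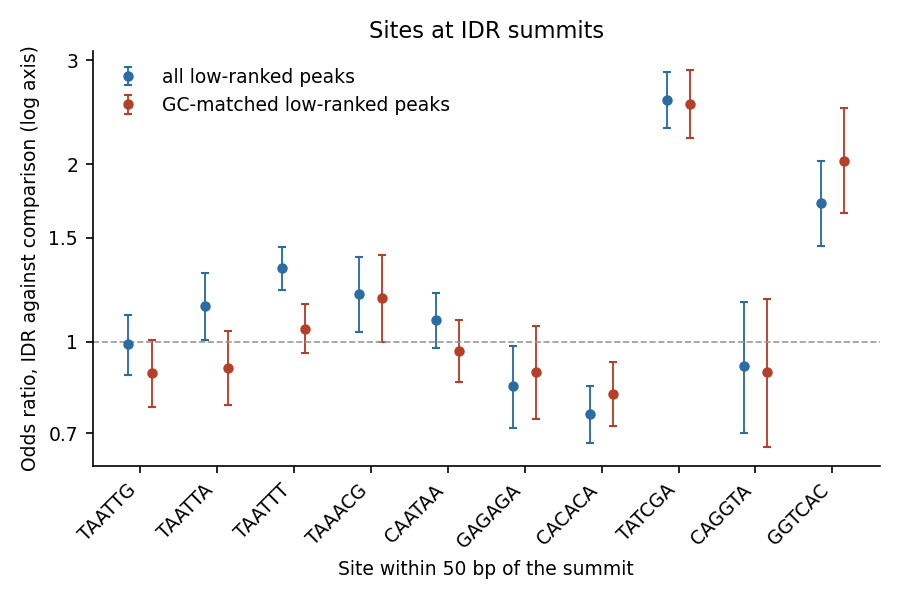
Odds ratio (log axis) of each site within 50 bp of IDR summits against all low-ranked peaks and against GC-matched low-ranked peaks, with 95% intervals; the dashed line marks 1. TATCGA (2.57 and 2.53) and GGTCAC (1.72 and 2.03) lie above 1 in both comparisons, and TAATTG (0.990 and 0.886) in neither.

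Of 13968 protein-coding genes, 3761 (26.9%) had an IDR summit within 1 kb of a TSS. Of the 17 gene lists fixed before the data were examined, 2 differed from all other genes. Cytoplasmic ribosomal protein genes had the highest share: 77 of 92 had a summit (83.7%, interval 74.5 to 90.6) against 26.5% of other genes (odds ratio 14.2, interval 8.08 to 26.6, adjusted p = 8.77e-29, Fisher's exact test). The strongest were at RpS27 (signal 1248, 3 bp from the TSS), RpL7 (1078), RpL34b (906) and RpL14 (755). Chemosensory receptor genes, most of which act in mature sense organs, had a low share: 6 of 179 had a summit (3.35%, interval 1.24 to 7.15, odds ratio 0.0927, interval 0.0335 to 0.206, adjusted p = 4.26e-16, Fisher's exact test). The strongest of these were at Or9a, Ir60e, Gr32a and Gr63a. Only 21 of the 179 had a summit of any pooled peak, and among genes with one the share was still lower but did not pass (28.6% against 47.1%, adjusted p = 0.527, Fisher's exact test).

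The lists of developmental regulators did not pass with the 1 kb window and all other genes as background. None of 8 Hox genes had an IDR summit within 1 kb of a TSS (exact upper limit 36.9%), and 9 of 58 other homeobox genes had one (15.5%, odds ratio 0.497, interval 0.215 to 1.02, adjusted p = 0.193, Fisher's exact test). The strongest of the 9 was at Dll, a limb patterning gene (2R, 24814579 to 24814900, signal 552), followed by the heart regulator tin (signal 231), eyg (213) and the eye regulator ey (188). Segmentation and temporal genes had 2 of 22, at ftz-f1 (signal 374) and bowl (179). Proneural and neural precursor genes had 2 of 19, at the asymmetric division genes numb (387) and brat (292). Notch pathway genes had 4 of 21, at Su(H) (258), neur (219), E(spl)m3-HLH (185) and N (131), with the Su(H) peak unmatched in replicate 1. The Wnt, Hedgehog, Dpp and EGFR list had 11 of 28 (39.3%), among them nkd (305), spi (223), ci (220) and brk (193). Adjusted p for these lists ran from 0.193 to 0.756 by Fisher's exact test.

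The lists of embryonic tissue markers did not pass either. Sensory organ genes had 4 of 21, at cpo (signal 436), neur, Rfx (193) and nan (136). Neuronal differentiation genes had 2 of 24 (8.33%, odds ratio 0.246, adjusted p = 0.193, Fisher's exact test), at elav, a neuron-specific RNA-binding protein gene with a strong peak (X, 523294 to 523659, signal 1046), and Syx1A (146). Axon guidance genes had 10 of 22 (45.5%, adjusted p = 0.193, Fisher's exact test), with PlexA (274), Lar (226), unc-5 (211) and Lac (192) strongest. Glial genes had 7 of 17, led by the blood-brain barrier receptor gene moody (X, 2050141 to 2050433, signal 890), Gli (171), loco (160) and nrv2 (149). Muscle genes had 5 of 21, with sls (359), tin, mbc (173) and TpnC73F (165). Epidermis and trachea genes had 7 of 18, with the tracheal regulator trh (346), crb (226), bnl (188) and shg (153). Gut, fat body and haemocyte genes had 5 of 20, with fkh (481), ush (244), Hnf4 (204) and Cad87A (115), the last without a match in replicate 1. Germline genes had 4 of 14, at gcl (284), bgcn (279), bam (183) and vas (154), and heat shock genes 8 of 19 (42.1%), led by Hsp83 (1164), Hsp68 (258), Hsp27 (236) and Hsp22 (212). For the lists without an adjusted p above, it lay between 0.296 and 1 by Fisher's exact test.

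Matched on TSS number and gene length, the neuronal differentiation, other homeobox and segmentation lists were also lower than expected, with 2 genes against 10.1, 9 against 18.8 and 2 against 7.66 (adjusted permutation p = 0.00283, 0.0159 and 0.0330). With a TSS window of 5 kb, the other homeobox genes (19.0% against 44.2%) and the neuronal differentiation genes (12.5% against 44.2%) were lower (adjusted p = 0.000495 and 0.00642, Fisher's exact tests). The homeobox list was also lower with replicate 1 alone (10.3% against 26.7%, adjusted p = 0.0235) but did not pass with replicate 3 alone (22.4% against 27.5%, adjusted p = 0.668, Fisher's exact tests). None of the neuronal differentiation, other homeobox and segmentation lists passed with a 500 bp window (adjusted p = 0.0947, 0.400 and 0.400, Fisher's exact tests) or with peaks assigned to the nearest TSS at any distance. In the latter the homeobox list stood at 19.0% against 22.0% and the segmentation list at 22.7% against 22.0% (adjusted p = 0.949 and 1, Fisher's exact tests). With that assignment, the axon guidance and the Wnt, Hedgehog, Dpp and EGFR lists were higher (adjusted p = 0.0150 and 6.13e-05, Fisher's exact tests). Neither passed with the 5 kb window (adjusted p = 1 and 0.0880, Fisher's exact tests) or matched on TSS number and gene length (adjusted permutation p = 0.643 and 0.990).

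**Figure D4:**
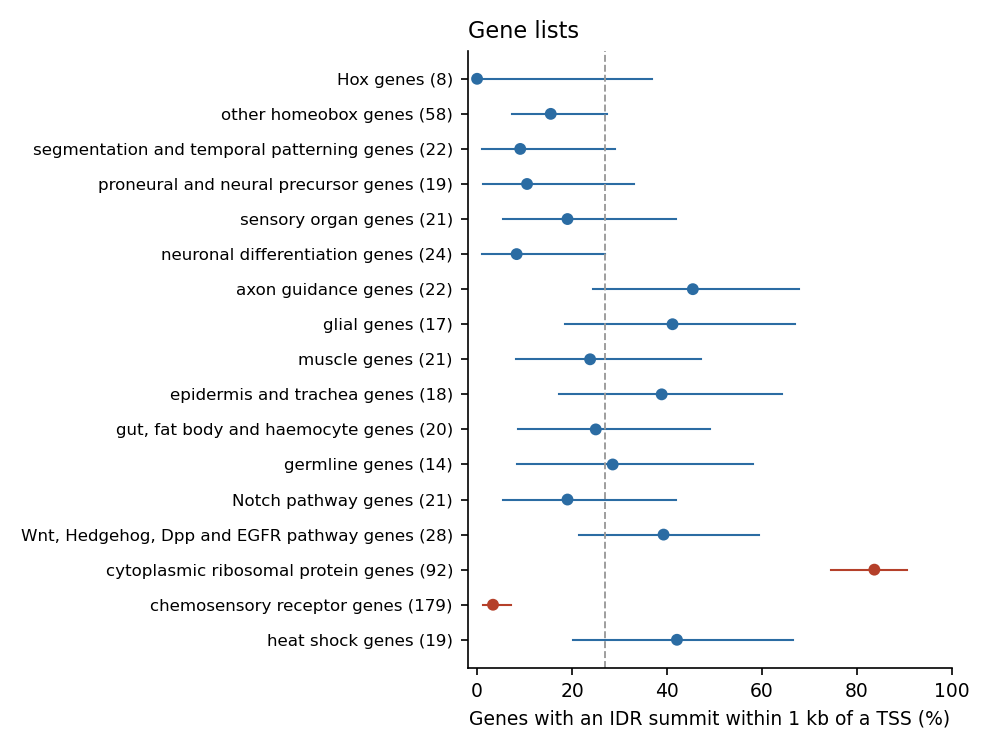
Share of genes (%) in each list with an IDR summit within 1 kb of a TSS, with exact 95% intervals; the number of genes stands in brackets, red marks an adjusted p under 0.05, and the dashed line is the share over all 13968 genes (26.9%). Ribosomal protein genes (83.7%) and chemosensory receptor genes (3.35%) stand apart.

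Peaks were dense around B-H2 and its upstream neighbour Fim, and absent from the IDR list at B-H1. The B-H2 gene spans X 17314581 to 17324175 on the plus strand. Within 20 kb of its TSS lay 8 IDR peaks and 32 pooled peaks, and within 40 kb 15 and 53. At other genes the median within 20 kb was 2 IDR peaks and 11 pooled peaks. Of 13967 other genes, 326 had at least 8 IDR peaks and 163 at least 32 pooled peaks. One IDR summit was 187 bp upstream of the TSS (17314202 to 17314585, signal 175) and another in intergenic sequence 1037 bp upstream (17313352 to 17313735, signal 166). Of the 15, 8 had their nearest TSS at Fim, 5 at B-H2, 1 at CG8661 and 1 at CG5445. The 2 bins of 10 kb from 17290001, over Fim and CG5445, held 14 and 10 pooled summits, and the next 2, which contain B-H2, held 8 and 2. The strongest lay at a promoter of Fim (17292049 to 17292348, signal 481), and the next 16235 bp downstream of the B-H2 TSS in intergenic sequence (17330679 to 17330948, signal 324). All 15 were matched in both replicates, as were 98.8% of all IDR peaks. Those with summits at 17294320 and 17294523 were matched to the same peak in each replicate. B-H1 (X, 17397478 to 17403278), whose TSS is 82897 bp from that of B-H2, had no IDR peak and 5 pooled peaks within 40 kb. The nearest pooled summit was 149 bp from its TSS, with signal 67.7 and rank 8848.

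**Figure D5:**
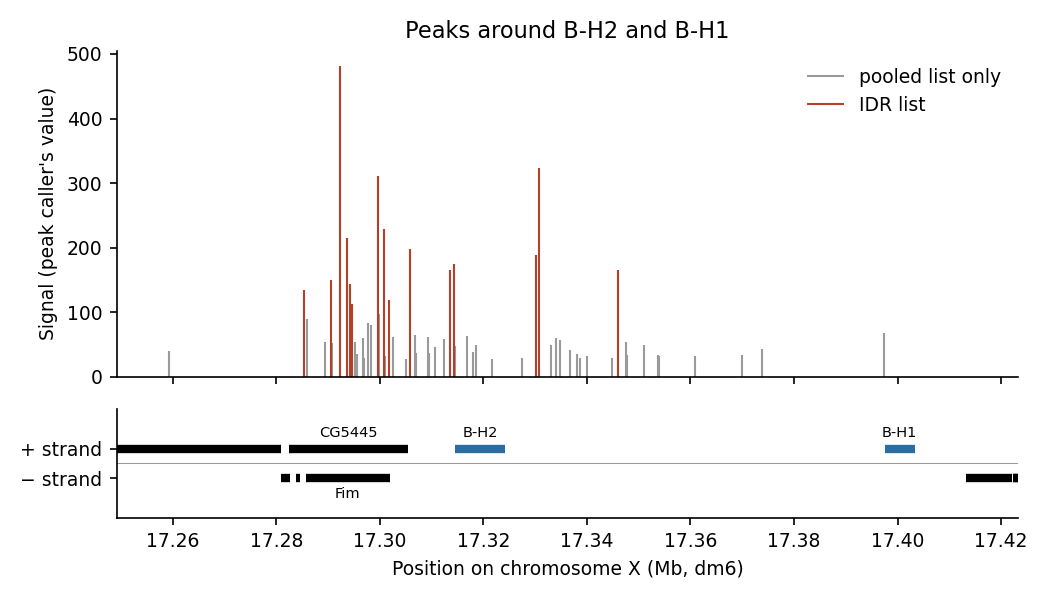
Signal (peak caller's units) at each pooled-list summit along chromosome X (Mb, dm6) around B-H2 and B-H1, with IDR peaks in red and other pooled peaks in grey, above the protein-coding genes on each strand. The 15 IDR peaks lie within 40 kb of the B-H2 TSS, and none lies within 40 kb of the B-H1 TSS.

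Windows of 50 kb held a median of 1 IDR summit. The fullest, on 2L (12000001 to 12050000), held 18, with Hacd1, Rh5 and Wdr81 among the genes with a summit at their TSS and 6 of the 18 at promoters. A window on 3R (16200001 to 16250000) with mtSSB and tara held 14, of which 2 were at promoters. The other 3 held 12 each, with 9, 5 and 11 at promoters: on 2L with Kr-h1, a hormone-responsive regulator, CG9135 and ND-51 (6050001 to 6100000), on 3L with simj, CG11811 and CG33493 (10650001 to 10700000), and on 3R with mura, CG9399 and Kap-alpha3 (9550001 to 9600000).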

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

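The alternatives with the stronger part of the IDR peaks, with genes that have a pooled summit as background and without peaks near B-H2 were chosen after seeing the data. A stricter IDR of 0.01 had been planned but could not be run, since the score column holds a constant; the stronger part of the IDR peaks by signal stood in for it. Promoter and X chromosome odds ratios kept their direction and passed in every alternative run. Without replicate 1 or without replicate 3, promoter odds ratios were 4.60 to 4.98 and those of the X 0.809 to 0.818, and the range over all promoter alternatives was 4.37 to 10.5. Replicate overlap ranged from 58.9% to 73.5% and rho from 0.61 to 0.71 over their alternatives. No paired analysis was possible because there is a single group. Merging overlapping IDR peaks left 4162 regions. TAATTG had an odds ratio of 0.855 with replicate 1 alone, where it passed on the lower side (p = 0.0131 adjusted over the 10 sites, Fisher's exact test), and 0.973 with replicate 3 alone. With replicate 1 alone TAATTA and CAATAA also passed, as higher (odds ratio 1.19 each, adjusted p = 0.0113 and 0.00237, Fisher's exact tests), and with replicate 3 alone neither did. In the stronger part of the IDR peaks TAATTA passed as higher (odds ratio 1.41) and GAGAGA as lower (0.721, adjusted p = 0.000155 and 0.00986, Fisher's exact tests). TAATTG moved to the other side of 1 with merged regions (1.01) and with the stronger part of the IDR peaks (1.05), without passing. The direction for TAATTG is therefore not set, and the cause was not tested. The count of 2 gene lists became 4 with a TSS window of 5 kb, 4 with the nearest TSS at any distance and 5 with genes matched on TSS number and length, and was 2 to 3 with either replicate alone; the cause was not tested. The lists gained were lower for other homeobox genes (5 kb, matched genes, replicate 1 alone), neuronal differentiation genes (5 kb, matched genes) and segmentation genes (matched genes), and higher for axon guidance and for Wnt, Hedgehog, Dpp and EGFR genes (nearest TSS). With replicate 3 alone the homeobox difference was -5.09 points and did not pass (adjusted p = 0.668, Fisher's exact test), against -16.4 points with replicate 1 alone. Ribosomal protein genes stayed higher in all these settings. Chemosensory receptor genes stayed lower in all of them, but with 21 genes left against genes with a pooled summit they did not pass (adjusted p = 0.527, Fisher's exact test), while neuronal differentiation genes passed as lower (adjusted p = 0.0256). Read depth is unknown, so it limits no value here in a way that can be stated.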

Other observations

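The tests on gene families, divergent genes, distal sites, homeobox genes as a comparison for B-H2 and GC matching of TATCGA were chosen after seeing the data. The tests of added transgene copies and of TAATTG at promoters were set before their results were seen.

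Genes were grouped into families by the start of their symbols. Of 42 families with at least 15 genes, 10 had an IDR summit within 1 kb of a TSS more often than other genes and 12 less often, and 9 and 8 of these also passed when matched on TSS number and gene length. Beyond the cytoplasmic ribosomal proteins, the higher families included mitochondrial ribosomal proteins (mRpL, 28 of 47, adjusted p = 2.02e-05, Fisher's exact test), autophagy genes (Atg, 13 of 20, 65.0%, adjusted p = 0.00155, Fisher's exact test) and secretory pathway genes (Sec, 11 of 19, adjusted p = 0.0192, Fisher's exact test). The lower ones included cuticle protein genes (Cpr, 2 of 71, adjusted p = 1.21e-06, Fisher's exact test), cytochrome P450 genes (Cyp, 6 of 85, adjusted p = 2.89e-05), odorant-binding protein genes (Obp, 1 of 51) and the Osi family (0 of 25). Histone genes (His, 3 of 115) were also low, but most are near-identical repeated copies, where read alignment is uncertain.

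At the 1179 distal IDR peaks, the screen of 2080 sites against the GC-matched low-ranked peaks left after removing promoter peaks found 29 sites more and 19 less frequent. GCGCCA led (7.97% against 3.54%, odds ratio 2.36, interval 1.81 to 3.07, adjusted p = 7.57e-07, Fisher's exact test), followed by the overlapping site AGCGCC (odds ratio 2.43, adjusted p = 3.31e-05, Fisher's exact test). The GC matching of this screen was to all IDR peaks, not to the distal ones. These GC-rich sites were not tested with matching among distal peaks. GTAAAC, which resembles the core of forkhead protein sites, was picked from the same screen. It ranked 6 there by p among the more frequent sites (9.50% against 5.92%, odds ratio 1.67, adjusted p = 0.00327, Fisher's exact test). With GC matching among distal peaks it had an odds ratio of 1.56 on the same IDR peaks (adjusted p = 0.00892, Fisher's exact test). The adjustment with this matching covered only the 10 panel sites and GTAAAC, not the 2080 sites of the screen. It is therefore no independent test of GTAAAC. In the panel, CAATAA (12.8% against 9.78% of all distal low-ranked peaks, odds ratio 1.36, adjusted p = 0.0125) and TAAACG (6.11% against 4.34%, odds ratio 1.43, adjusted p = 0.0334) passed by Fisher's exact test. With GC matching done among distal peaks, neither passed (odds ratios 1.20 and 1.37, adjusted p = 0.291 and 0.188, Fisher's exact tests).

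If the tagged transgene added copies of the B-H2 region, weak peaks around the gene could be raised along with strong ones. That would not hold if the control alignment carried the same copies. The 21 low-ranked peaks within 20 kb of the TSS lay at percentile 96.1 of the same count at other genes (median 8). That was the result predicted for added copies, though 621 of 13967 other genes reached that count. Dense binding would raise the count too, so it does not single out added copies. None of 66 homeobox and Hox genes reached 21, but 8 of the 21 summits lie inside other genes, and without such summits 3 of the 66 reached the 13 left at B-H2 (percentile 96.2). A long regulatory region like theirs therefore stays open, as does binding of B-H2 to its own locus, which was not tested. The labels do not say how much flanking DNA the insertion carries, nor settle whether these libraries are input, in which added copies could raise peaks too.

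The promoter excess was weighed against signal that collects at active promoters without a Bar site. At promoters, TAATTG was at 8.59% of IDR and 8.19% of low-ranked peaks (odds ratio 1.05, interval 0.905 to 1.22), as that explanation requires. That result cannot exclude binding of B-H2 through other sites, since the comparison peaks come from the same immunoprecipitation. The related sites TAATTA (7.36% against 5.40%, odds ratio 1.39, adjusted p = 0.00022) and TAATTT (19.7% against 14.7%, odds ratio 1.43, adjusted p = 7.66e-10) were higher at IDR promoters and GAGAGA lower (odds ratio 0.648, adjusted p = 4.47e-05, Fisher's exact tests), though over all peaks none of the 3 passed against GC-matched windows (odds ratios 0.904, 1.05 and 0.888). Base composition alone is argued against for TATCGA, which held against GC-matched windows (odds ratio 2.53). Recruitment of B-H2 by other promoter factors and a general affinity of the assay for open promoters both stay open. So does binding of B-H2 through related sites such as TAATTA. No control immunoprecipitation was analysed here.

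IDR promoter peaks often lay between genes transcribed in opposite directions. A summit with TSSs of at least 2 genes within 1 kb was seen for 1262 of 3098 IDR promoter peaks (40.7%) and 21.5% of 8671 low-ranked ones (odds ratio 2.51, interval 2.29 to 2.74, Fisher's exact test, p = 3.62e-91). Summits flanked by divergent TSSs made up 33.3% and 11.4% (odds ratio 3.87). The odds ratio of 2.51 is the pattern itself, so it excludes no explanation, and both a plain effect of more TSSs nearby and higher activity of such promoters stay open.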
